A study of Mus musculus with 16 samples.

How the data were processed

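RNA from whole mouse embryonic hearts at embryonic day 10.5 was measured by bulk RNA sequencing in 16 samples of 4 genotypes, with 4 samples each. The genotypes were wild type (WT), Tbx5 del/+, Tbx5 CreERT2/+ and Tbx5 CreERT2/del, where del and CreERT2 name altered Tbx5 alleles. Per the labels' protocols, RNA was extracted with Qiazol and a miRNeasy micro kit, and libraries were made with the Ovation RNA-seq system V2. Per the submitters' processing notes, TopHat2, featureCounts and edgeR were used with the mouse genome build mm9; tool versions, strand settings and filters are not given in the sources used here. Counting by strand is not stated, so reads of overlapping and antisense genes cannot be assigned to one of them.

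The authors deposited 1 table with 37991 genes. The per-sample values used are those the authors deposited as raw, non-normalized counts of reads per gene; per the submitters' processing notes they were made by featureCounts after alignment with TopHat2, and none is an expected count from a model. They are whole numbers and were used as they stand, without rounding. The authors' deposited comparisons give a log2 fold change per pair of genotypes, and the authors' deposited table also gives a p-value and an adjusted p-value for each of 14820 genes. Values from those comparisons are printed only where the authors' deposited table is named. A further 52 columns of per-sample or group-mean values and 2 columns without a name were not used. Of the genes, 415 carry no symbol in the table and are named by their identifier, and these took at most 0.117% of a library's counts. Gene positions are those of the deposited table in mm9. The tested gene types were taken by gene identifier from GENCODE release vM21, which gave a type for 14078 of 14612 tested genes; no coordinate of that release was used.

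Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with the default filter (14612 genes remained), library sizes were scaled by the TMM method, and a quasi-likelihood model with 1 mean per genotype was fitted to all 16 libraries, which left 12 residual degrees of freedom. The genotypes share 1 estimate of the spread in this model. A total of 7 contrasts were tested: each altered genotype against WT, the 3 comparisons among altered genotypes, and the interaction, which is CreERT2/del minus del/+ minus CreERT2/+ plus WT. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test over all tested genes, with a threshold of 0.05. Errors of log2 fold changes are standard errors, and levels are CPM, counts scaled to a common library size with TMM factors, with their SD over 4 libraries. Tbx5 was also compared with a two-sided exact permutation test of log2(CPM + 1), whose smallest possible p is 0.0286.

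A set of 27 gene lists was fixed before the data were examined. They cover reported Tbx5-responsive heart genes, heart muscle and chamber markers, ion channels, other heart cell types, blood, neighbouring embryonic tissues, cell cycle and stress responses, energy metabolism, mitochondrial transcripts, sex-linked genes and the chromosomal neighbourhood of Tbx5. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 26 lists with at least 3 tested members; the list of limb and body wall mesenchyme had 0 tested members. Each call was repeated with a correlation estimated from the data, and members were also adjusted over the list alone.

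The genes named in the text were chosen by a rule fixed before the data were examined. Tbx5 is named in every comparison. In each comparison with WT, the rule takes the 8 genes that rose and the 8 that fell with the lowest adjusted p among those past the threshold whose 4 libraries do not overlap the other 4, and in the other comparisons 4 and 4. Sex-linked genes and predicted genes are left out of that part. Where no gene passes, the 3 genes with the lowest p in each direction are given as values. From each list the rule adds up to 4 members past the threshold, or else the member with the lowest p. Of the genes that the rule names, 1 is left out of this text. Genes named beyond the rule are marked as chosen after their values were seen.

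The procedure was tested on simulated counts for CreERT2/del against WT, with 200 of 14612 genes changed: 25% of the 2-fold and 80% of the 4-fold changes were recovered, 3.67% of the calls were genes left unchanged, and 0 genes were called with no gene changed. These counts were drawn independently for each gene and hold no structure shared between genes. The rates may therefore differ in the real libraries. No pair of libraries of 1 genotype matched within sampling noise (chi-square per degree of freedom from 17.9 to 191.4), so all 16 were kept. The alternatives fixed beforehand were other size factors, no filter and a stricter filter (mean CPM of at least 5), DESeq2 1.42.0, limma-voom with quality weights, only the groups compared, the replicate number as a block, removal of erythroid genes, Xist as a covariate, another pseudocount for Tbx5, an estimated correlation for lists, and leaving out each library in turn. Chosen after the data were seen were the removal of the 6 most abundant genes that lack values in the authors' deposited table, the omission of the 3 libraries with the lowest share of mitochondrial ribosomal RNA, and covariates for that share and for 7SK.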

Results

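Hearts of midgestation mouse embryos were profiled by bulk RNA sequencing to compare animals with altered copies of Tbx5, which encodes a T-box transcription factor of heart and forelimb development. The 16 libraries fall into WT, Tbx5 del/+, Tbx5 CreERT2/+ and Tbx5 CreERT2/del, with 4 libraries each. The labels do not say whether the 4 libraries of a genotype came from separate embryos or litters. Each genotype held libraries high in Xist and libraries high in the Y-linked gene Kdm5d, so not all 4 came from 1 embryo. In WT 1 and 2 Xist was at 171.3 and 178.1 CPM, and in WT 3 and 4 Kdm5d was at 22.6 and 35.92 CPM. The sexes were not balanced: Xist was high in del/+ 3 alone (218.4 CPM) but in CreERT2/+ 2, 3 and 4 (142.6 to 615.1 CPM). CreERT2/del 2 held both, with Xist at 31.19 CPM and Kdm5d at 19.85 CPM, so these genes do not assign it to 1 sex. The p-values measure only the spread between these samples, part of which may be technical. Total counts ran from 21436305 in CreERT2/+ 3 to 42731841 in WT 2. Mitochondrial ribosomal RNA (mt-Rnr1 and mt-Rnr2) took 42.3% of the counts in CreERT2/+ 3, 53.6% in CreERT2/del 3, 60.6% in WT 4 and 62.3% to 78.3% in the other 13. The counts outside these genes ran from 6611755 to 16796193. Those 3 libraries also stood apart on the first principal component, which held 20.2% of the variance: they lay at 82.0, 36.0 and 56.2, and the other 13 lay between -34.2 and 1.42.

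**Figure D1:**
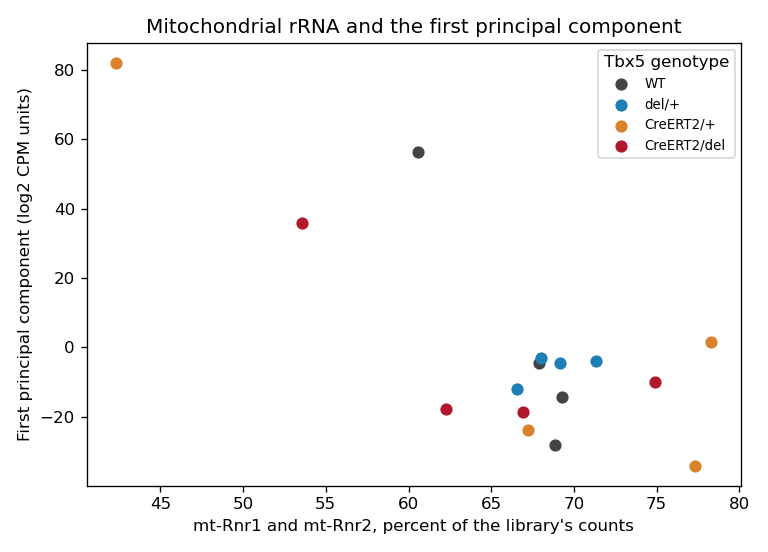
Each point is 1 of the 16 libraries, coloured by genotype, with the percent of counts from mt-Rnr1 and mt-Rnr2 on the x axis and the first principal component of log2 CPM on the y axis. The libraries CreERT2/+ 3, WT 4 and CreERT2/del 3 lie at 82.0, 56.2 and 36.0, above the other 13.

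Tbx5 itself (ENSMUSG00000018263, chromosome 5, 120284672 to 120335227 in mm9) was expressed in all genotypes. Its level was 19.7 ± 5.24 CPM in WT, 31.2 ± 7.18 in del/+, 24.4 ± 9.91 in CreERT2/+ and 22.4 ± 1.79 in CreERT2/del (SD, n = 4). In the exact permutation test, no difference from WT passed. By that exact test the log2 differences were 0.65 for del/+ (p = 0.0571), 0.26 for CreERT2/+ (p = 0.486) and 0.21 for CreERT2/del (p = 0.371). In edgeR's model the log2 changes were 0.66 ± 0.25, 0.31 ± 0.25 and 0.18 ± 0.25 (SE), with adjusted p of 0.708 to 1. A count over the whole gene cannot show which part of it an altered allele lacks, so these values do not check the genotypes. Without WT 1, the del/+ difference was 0.76 with an exact p of 0.0286.

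The comparison of CreERT2/del with WT asks how hearts with both Tbx5 copies altered differ from normal ones. Gja5, which encodes the gap junction protein connexin 40 of atrial and conduction tissue, fell 12.2-fold, from 53.4 ± 16.5 CPM in WT to 4.39 ± 1.04 (SD, n = 4). Ap3b2, a subunit of the neuronal AP-3 vesicle adaptor, fell 23.7-fold, from 6.17 ± 1.36 to 0.244 ± 0.0829 CPM. Tbx3, a T-box gene of the conduction system, fell 2.77-fold. Kcna1, a voltage-gated potassium channel, rose 29.4-fold from 0.851 ± 0.251 CPM to 25.1 ± 10.04. In total 27 genes rose and 22 fell.

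The log2 changes were -3.61 ± 0.26 for Gja5 (chromosome 3, 96708616 to 96881339) and -4.57 ± 0.33 for Ap3b2 (chromosome 7, 88605285 to 88638811), each with an adjusted p of 1.45e-08. All 4 CreERT2/del libraries lay below all 4 WT libraries for both genes. Stard10, a lipid transfer protein, fell by 2.05 ± 0.33 (adjusted p = 0.0048), and Ntn1, the secreted guidance cue netrin 1, fell by 2.16 ± 0.33 (adjusted p = 0.00241). Fam134b, a receptor for turnover of the endoplasmic reticulum, fell by 1.61 ± 0.24, and Cpne5, a calcium-dependent membrane-binding protein, fell by 1.47 ± 0.25. Fam70a, which encodes a membrane protein, fell by 1.43 ± 0.24. BC053393 had 171 counts in the WT libraries and 2 in the CreERT2/del libraries, both in CreERT2/del 1, a ratio of 84.1 with a 95% counting interval of 22.9 to 700.3. Intervals of this kind cover counting error only.

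Among the genes that rose, Otx1, a homeobox gene of the forebrain, went up by 3.92 ± 0.39 (log2, adjusted p = 3.79e-06) and Tesc, a calcium-binding protein, by 2.48 ± 0.29 (adjusted p = 5.4e-05). Shisa3, an inhibitor of Wnt and FGF signalling, rose by 3.21 ± 0.46, and Med18, a subunit of Mediator, by 1.90 ± 0.27. Ddc, the decarboxylase of dopamine and serotonin synthesis, rose by 1.39 ± 0.21 from 7.80 ± 0.856 CPM to 20.5 ± 4.76. The growth factor gene Pdgfc rose by 1.55 ± 0.28 and Ttyh2, a member of the tweety family, by 1.20 ± 0.21.

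The atrial markers were lower as a group (camera adjusted p = 5.91e-06; with an estimated correlation, adjusted p = 0.00295), with a median log2 change of -0.48. Gja5 and Stard10 fell, and 4 of the 10 passed when adjusted over the list alone. Of the others, Kcnj3, a potassium channel of atrial muscle, had -1.43 ± 0.34 (adjusted p = 0.0781) and Kcna5 -1.17 ± 0.39. The muscle proteins Myl7 and Myl4 had -0.21 each and the hormone gene Nppa -0.03. These other markers are named after their values were seen. Ion channels, gap junctions and calcium handling were lower as a group (adjusted p = 5.91e-06; with an estimated correlation, adjusted p = 0.0235), with 2 of 23 past the threshold, and 6 adjusted over the list alone. This list stood at 3.77 mean log2 CPM in WT 4, a library with little mitochondrial ribosomal RNA, and at 3.30 to 3.33 in the other WT libraries. The reported Tbx5-responsive genes were also lower (adjusted p = 4.8e-04; with an estimated correlation, adjusted p = 0.0104): 3 of 14 fell, and over the list alone 5 fell and 1 rose.

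The epicardium markers, of the cell layer that covers the heart, were lower as a group (adjusted p = 5.91e-06; with an estimated correlation, adjusted p = 0.00295), with a median of -0.54. None of the 10 passed over all genes by edgeR, and 5 fell when adjusted over the list alone, with Aldh1a2, the enzyme of retinoic acid synthesis, lowest at -1.14 ± 0.26. The trabecular list was called lower (adjusted p = 0.0043; with an estimated correlation, adjusted p = 0.0235) with a median of -0.03 and a mean of -0.42, where Gja5 fell among its 11 members and 3 fell over the list alone. This call was lost without CreERT2/del 3 (adjusted p = 0.0608) and without the 3 libraries low in mitochondrial ribosomal RNA (adjusted p = 0.201), its highest value under any alternative. Fhl2, a muscle LIM protein, had -0.74 ± 0.18 and the hormone gene Nppb 0.87 ± 0.34, neither past the threshold over all genes. Both are named after their values were seen.

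The other 21 lists did not pass (adjusted p from 0.0517 to 0.932). The sarcomere list had a median of 0.05 over 22 genes, with the ventricular myosin gene Myh7 at 0.66 ± 0.24, and the ventricular list had a median of 0.16. The cardiac transcription factors had a median of 0.13, with only Tbx3 past the threshold. Compact myocardium had a median of 0.10, endocardium and endothelium -0.04, cushion and valve mesenchyme -0.04, and second heart field and Hedgehog genes 0.00. Outflow tract signals had a median of 0.21, neural crest and glia -0.15, erythroid cells -0.24, leukocytes and macrophages 0.51, and endoderm and liver 0.42. The cell cycle median was 0.04, that of p53 targets -0.10 with a mean of 0.03, of the integrated stress response 0.06, and of immediate early and heat shock genes 0.24. Glycolysis and hypoxia genes had a median of 0.07, oxidative phosphorylation genes -0.09, mitochondrial transcripts 0.18 and sex-linked genes -0.17 with an upward test. The neighbours of Tbx5 on its chromosome had a median of 0.04 with a mean of -0.02.

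The count of 49 genes became 121 with DESeq2, 121 with limma-voom, 189 with no filter, 13 with the stricter filter, 95 without the 3 libraries low in mitochondrial ribosomal RNA, 129 with that share as a covariate and 18 with 7SK as a covariate, under which Tbx3, Ntn1, Cpne5, Med18 and Ddc among others and the ion channel list (adjusted p = 0.0845, the highest of its 24 alternatives) no longer passed. It was 26, 28, 31 and 30 without WT 1, 2, 3 and 4 in turn, 30, 24 and 25 without CreERT2/del 1, 2 and 4, and 99 without CreERT2/+ 3. Tbx3 did not pass without WT 1, 2 or 4 or CreERT2/del 1, 3 or 4 (adjusted p from 0.0643 to 0.104). Ttyh2 did not pass without WT 2 (0.0546) or CreERT2/del 2 (0.0518), nor Pdgfc without WT 1 (0.05001). Without WT 3 or WT 4, 8 lists were called.

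**Figure D2:**
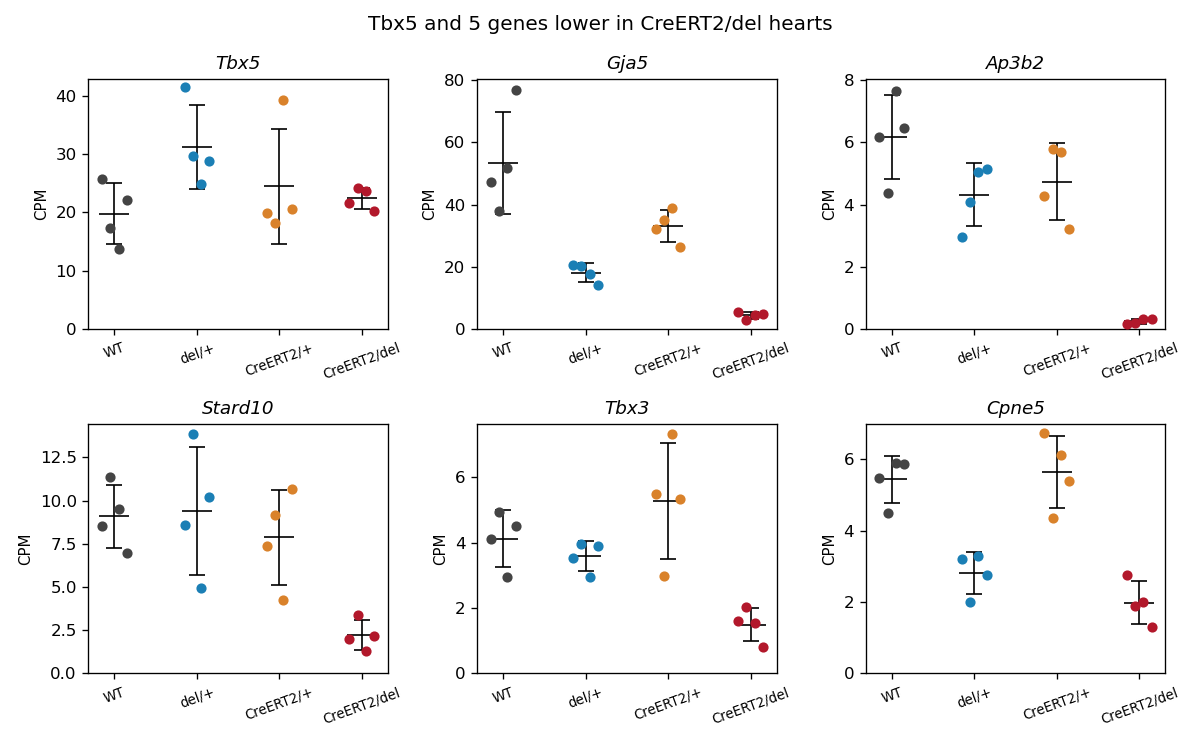
CPM of Tbx5, Gja5, Ap3b2, Stard10, Tbx3 and Cpne5 in each library (points), with the mean and SD of the 4 libraries of each genotype (bars), on linear axes from 0. For Gja5 the mean is 53.4 CPM in WT, 18.1 in del/+, 33.2 in CreERT2/+ and 4.39 in CreERT2/del.

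The comparison of del/+ with WT asks how hearts labelled with 1 del allele differ from WT. Gja5 fell 2.94-fold to 18.1 ± 3.00 CPM (SD, n = 4; log2 -1.56 ± 0.23, adjusted p = 0.00185). By edgeR it was the only gene that fell, with 849 genes at an unadjusted p under 0.05 in either direction; DESeq2 called 5 lower and limma-voom 2. Kcna1 rose 44.1-fold to 37.6 ± 10.6 CPM, and 7SK, the small nuclear RNA that holds the elongation factor P-TEFb inactive, rose 19.96-fold from 17.0 ± 8.45 to 339.0 ± 241.0 CPM. In all, 14 tested entries carry the name 7SK, and the values given are those of the entry on chromosome 9 that held 92.9% of their counts. Otx1 rose 12.04-fold and Med18 5.61-fold. In total 16 genes rose and 1 fell, and for the genes named here the 4 del/+ libraries did not overlap the 4 WT libraries.

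The log2 changes were 5.46 ± 0.36 for Kcna1 (chromosome 6, 126586481 to 126595819; adjusted p = 7.19e-09), 3.59 ± 0.39 for Otx1 and 2.49 ± 0.28 for Med18. For 7SK the change was 4.32 ± 0.57 (adjusted p = 5.66e-04), and 3.71 ± 0.52 without del/+ 2. Unc5d, a netrin receptor, rose by 4.603 ± 0.65, and by 3.88 ± 0.59 without del/+ 2. Fam3c, a secreted protein, rose by 1.63 ± 0.23, Ttyh2 by 1.51 ± 0.21 and Tesc by 1.91 ± 0.29. The histone genes Hist1h2ai, Hist1h4c and Hist2h2ac and the small nucleolar RNA snoZ40 were also among the 16; they were named after their values were seen, and near-identical histone copies make their counts uncertain.

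The trabecular list was called lower (adjusted p = 0.0468), and this call was lost with an estimated correlation (adjusted p = 0.173). It was also lost without WT 1, 3 or 4, del/+ 1, 3 or 4, any single CreERT2/+ library or CreERT2/del 1, with an adjusted p from 0.0578 to 0.187 and 0 lists called, and without WT 2 the count was 2 lists. Gja5 fell among its 11 members, and 2 fell over the list alone. The other 25 lists did not pass (adjusted p from 0.284 to 0.931). The atrial markers had a median of -0.11 and the sarcomere list 0.02. The endoderm and liver list had a median of 1.33 and a downward test, with albumin (Alb) at 51.4 CPM in del/+ 1 and at most 0.04 CPM in the other del/+ libraries.

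In the authors' deposited table, an adjusted p under 0.05 was given for 4 genes between del/+ and WT, all higher in del/+, and for 5 genes between CreERT2/del and WT. The fall of Gja5 in del/+ did not pass there (log2 -1.54, adjusted p = 0.983 in the authors' deposited table). Its fall in CreERT2/del against WT did (log2 -3.599, adjusted p = 0.015 in the authors' deposited table). The count of 17 genes became 41 with DESeq2, 29 with limma-voom, 120 with no filter, 10 with the stricter filter, 37 with only the groups compared, 43 without the 3 libraries low in mitochondrial ribosomal RNA, 43 with that share as a covariate, 38 without CreERT2/+ 3, and 1 with 7SK as a covariate, where Gja5 had -0.97 (adjusted p = 0.311).

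The comparison of CreERT2/+ with WT asks whether the CreERT2 allele alone changes expression. Kcna1 rose 27.7-fold to 23.6 ± 7.23 CPM (SD, n = 4), Otx1 13.8-fold, Med18 4.59-fold and Tesc 3.21-fold. The log2 changes were 4.79 ± 0.35 (adjusted p = 5.93e-08), 3.79 ± 0.39 (adjusted p = 1.45e-05), 2.20 ± 0.28 (adjusted p = 3.33e-04) and 1.68 ± 0.29 (adjusted p = 0.0256). Hist1h2ai also rose, with libraries that overlapped WT. Gja5 was at 33.2 ± 5.22 CPM, a log2 change of -0.69 ± 0.23 that did not pass (adjusted p = 1.0). No gene fell by edgeR, with 542 genes at an unadjusted p under 0.05 in either direction; DESeq2 called 1 lower and limma-voom 0.

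No list was called by camera, with 3 lists at an unadjusted p under 0.05, 0 by fry and a lowest adjusted p of 0.826 with an estimated correlation. The cardiac transcription factors had a median of 0.20 and the atrial markers 0.18. In the authors' deposited table, an adjusted p under 0.05 was given for 0 genes of this pair, with a lowest value of 0.0751 and 446 genes at an unadjusted p under 0.05. The 5 calls became 21 with DESeq2, 21 with limma-voom, 73 with no filter, 33 without the 3 libraries low in mitochondrial ribosomal RNA, 21 with that share as a covariate and 2 with 7SK as a covariate. They became 3, 3, 8 and 3 without WT 1, 2, 3 and 4, 8 without del/+ 2, and 3, 3, 34 and 3 without CreERT2/+ 1, 2, 3 and 4. Tesc did not pass without WT 1, 2 or 4 or CreERT2/+ 1, 2 or 4 (adjusted p from 0.0904 to 0.208). The lists called were 1 and 2 without WT 2 and 4, and 1, 2 and 1 without CreERT2/+ 1, 2 and 3.

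**Figure D3:**
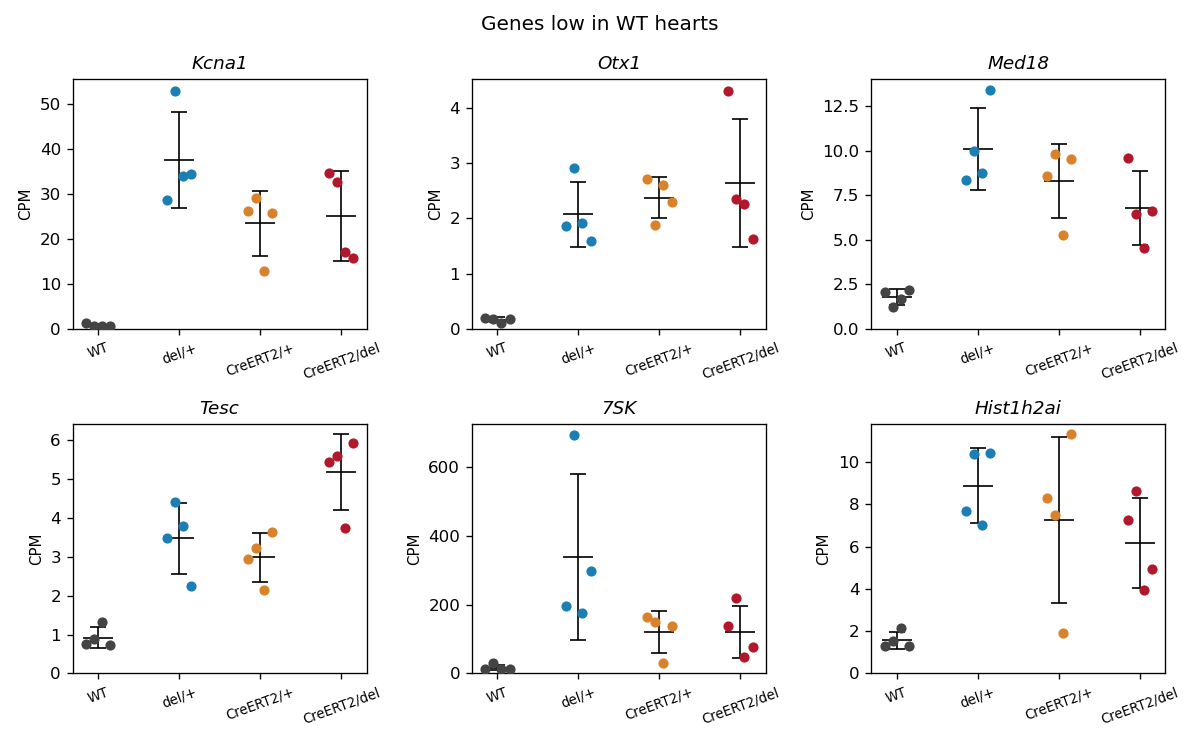
CPM of Kcna1, Otx1, Med18, Tesc, 7SK and Hist1h2ai in each library (points), with the mean and SD of the 4 libraries of each genotype (bars), on linear axes from 0. Kcna1 has a mean of 0.851 CPM in WT, 37.6 in del/+, 23.6 in CreERT2/+ and 25.1 in CreERT2/del.

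The same WT libraries entered these comparisons. Kcna1, Otx1, Med18, Tesc and Hist1h2ai rose in all 3, and 13 genes rose in both CreERT2/del and del/+. Independent lists would share 0.0296, and simulated unchanged groups with common simulated controls shared 0 in 20 fits. With the WT libraries split 2 and 2 between the heterozygotes, 2 or 3 genes were shared, Kcna1 and Otx1 each time. Across genes, which are not independent replicates, the log2 changes of del/+ and CreERT2/+ had Pearson's r of 0.525 and Spearman's rho of 0.460. Simulated unchanged groups with common WT libraries, which were simulated too, gave a mean r of 0.483 and at most 0.509 in 100 simulations. The simulation drew each gene independently, so it holds no structure shared between genes and its range may be too narrow. The covariance was 0.0908 against 0.0764 simulated, a difference of 0.0144, and with the WT libraries split the mean r was 0.043 (-0.0727 to 0.135).

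The comparison of CreERT2/del with del/+ asks what the CreERT2 allele adds to the del allele. Ap3b2 fell 16.5-fold, Stard10 4.27-fold and Gja5 4.14-fold. The log2 changes were -4.05 ± 0.33 (adjusted p = 3.54e-07), -2.09 ± 0.33 (adjusted p = 0.0136) and -2.05 ± 0.24 (adjusted p = 1.82e-04), and the 4 libraries of each side did not overlap. No gene rose by edgeR, with 742 genes at an unadjusted p under 0.05 in either direction; DESeq2 called 7 higher and limma-voom 1. Tbx3 had -1.27 ± 0.30 (adjusted p = 0.306) and Tbx5 -0.48 ± 0.25. The authors' deposited table gave 0 genes of this pair an adjusted p under 0.05, with a lowest value of 0.124 for Ap3b2.

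The atrial markers (adjusted p = 7.42e-05; with an estimated correlation, adjusted p = 0.0097), the epicardium markers (adjusted p = 7.61e-04; with an estimated correlation, adjusted p = 0.0161) and the reported Tbx5-responsive genes (adjusted p = 0.00127; with an estimated correlation, adjusted p = 0.0164) were lower as groups, the last with a median of 0.08 and a mean of -0.36. Of the 10 atrial markers 2 fell, and 3 over the list alone; 0 epicardium markers passed by edgeR, and 1 Tbx5-responsive gene fell, with 5 over the list alone. The ion channels (adjusted p = 0.00111) and erythroid cells (adjusted p = 0.0112) were also called lower, but with an estimated correlation their adjusted p was 0.13 and 0.789. Outflow tract signals (adjusted p = 0.0384) and endoderm and liver (adjusted p = 0.0398, against a median of -1.44) were called higher, with an adjusted p of 0.21 and 0.654 with an estimated correlation. The 3 calls became 22 with DESeq2, 9 with limma-voom, 65 with no filter, 13 with only the groups compared, 16 without the 3 libraries low in mitochondrial ribosomal RNA, 6 with that share as a covariate and 6 without CreERT2/+ 3; Stard10 lost its call with Xist (adjusted p = 0.0881) or 7SK (0.104) as a covariate and without del/+ 2 or 4 or CreERT2/del 1, 3 or 4 (0.0618 to 0.11).

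The comparison of CreERT2/del with CreERT2/+ asks what the del allele adds to the CreERT2 allele. Ap3b2 fell 18.3-fold, Gja5 7.57-fold, Tbx3 3.56-fold, Stard10 3.56-fold and Cpne5 2.87-fold. Shisa3 rose 6.05-fold, Tnc, the matrix protein tenascin C, 3.27-fold and Ddc 2.71-fold. In total 3 genes rose and 8 fell, and the 4 libraries of each side did not overlap for those named. The log2 changes were -4.19 ± 0.33 for Ap3b2 (adjusted p = 1.82e-07), -2.92 ± 0.25 for Gja5 (adjusted p = 5.06e-07), -1.83 ± 0.30 for Tbx3 (adjusted p = 0.0137) and 1.44 ± 0.21 for Ddc (adjusted p = 0.00293). Tbx5 had -0.13 ± 0.25. For this pair too, 0 genes had an adjusted p under 0.05 in the authors' deposited table. Its lowest values were 0.0773 for Ap3b2 and 0.393 for Gja5, Cacna2d2 and Tbx3.

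The atrial markers were lower as a group (adjusted p = 1.66e-11; with an estimated correlation, adjusted p = 1.84e-04), with a median of -1.09 and all 10 negative; 2 fell and 4 over the list alone. Ion channels (adjusted p = 1.17e-08), reported Tbx5-responsive genes and epicardium (adjusted p = 1.7e-04 each) and the trabecular list (adjusted p = 0.00618) were lower too, with an adjusted p of 0.00683, 0.00683, 0.00683 and 0.0331 with an estimated correlation. Glycolysis and hypoxia genes were called higher (adjusted p = 7.36e-05) with a median of 0.31 and 19 of 20 positive, as were endoderm and liver (adjusted p = 2.49e-04), cell cycle (adjusted p = 0.00701) and the integrated stress response (adjusted p = 0.0388). These 4 calls were lost with an estimated correlation, with an adjusted p of 0.117, 0.158, 0.316 and 0.337. The 11 calls became 43 with DESeq2, 18 with limma-voom, 92 with no filter, 5 with the stricter filter, 2 with only the groups compared, where Tbx3, Cpne5 and Stard10 had an adjusted p of 0.118 each, and 27 with mitochondrial ribosomal RNA as a covariate. They became 4 and 21 without CreERT2/+ 1 and 3, and 7, 4 and 3 without CreERT2/del 2, 3 and 4. In those fits that left out 1 library, Tbx3 did not pass without CreERT2/+ 1 or CreERT2/del 3 or 4 (adjusted p from 0.0507 to 0.0731), nor Cpne5 without CreERT2/+ 1 or CreERT2/del 2, 3 or 4 (0.0583 to 0.0847). Stard10 did not pass without CreERT2/+ 1, 2 or 4 or CreERT2/del 1, 3 or 4 (0.0767 to 0.117), nor Shisa3 without CreERT2/+ 1, 2 or 4 or CreERT2/del 2, 3 or 4 (0.0677 to 0.103). Tnc did not pass without WT 2, del/+ 2, 3 or 4, CreERT2/+ 1, 2 or 4 or any single CreERT2/del library (0.0522 to 0.163). The trabecular list was not called without CreERT2/del 3 (adjusted p = 0.103).

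The comparison of CreERT2/+ with del/+ asks whether the heterozygotes differ. No gene passed by edgeR, with 611 at an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0. The genes with the lowest p were Cpne5 (1.00 ± 0.25), Gja5 (0.87 ± 0.23) and Pddc1 (1.26 ± 0.36) on the higher side and Car4, a carbonic anhydrase (-0.90 ± 0.24), Xab2, a splicing and repair factor (-0.97 ± 0.26), and Tnnt1, slow skeletal troponin T (-0.83 ± 0.22), on the lower side, each with an adjusted p of 0.997. Cell cycle (adjusted p = 2.37e-04, median -0.25) and glycolysis and hypoxia genes (adjusted p = 0.00615) were called lower and atrial markers (adjusted p = 0.0161, median 0.35) and ion channels (adjusted p = 0.0412) higher. All 4 list calls were lost with an estimated correlation, with an adjusted p of 0.201, 0.417, 0.181 and 0.417. Tbx5 had -0.35 ± 0.25. With no filter 36 genes passed. The lists called were 2 without del/+ 1 and 1 without CreERT2/+ 2.

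The interaction asks whether the change in CreERT2/del differs from the sum of the changes in both heterozygotes. Ap3b2 lay further down than that sum by a log2 value of -3.68 ± 0.41 (adjusted p = 8.13e-05). Kcna1 (-5.37 ± 0.45, adjusted p = 7.12e-07), Otx1 (-3.45 ± 0.50, adjusted p = 0.00228) and Med18 (-2.78 ± 0.38, adjusted p = 0.00117) lay below the sum because each was about as high in CreERT2/del as in either heterozygote. In total 6 genes passed, all below the sum, with 634 at an unadjusted p under 0.05; DESeq2 called 0 above the sum and limma-voom 0. Gja5 had -1.36 ± 0.33 (adjusted p = 0.352), so a departure from the sum was not shown for it, and Tbx5 had -0.79 ± 0.35.

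The atrial markers were below the sum as a group (adjusted p = 3.78e-05; with an estimated correlation, adjusted p = 0.00763), with 0 of 10 past the threshold by edgeR and 3 over the list alone. The calls for ion channels (adjusted p = 0.00645), reported Tbx5-responsive genes, endoderm and liver and the neighbours of Tbx5 (adjusted p = 0.0285 each) and glycolysis and hypoxia genes (adjusted p = 0.0422) were lost with an estimated correlation, with an adjusted p of 0.271, 0.115, 0.551, 0.402 and 0.551; the endoderm and liver list had an upward test and a median of -0.12. The 6 calls became 16 with DESeq2, 13 with limma-voom, 73 with no filter, 24 without the 3 libraries low in mitochondrial ribosomal RNA, 15 with that share as a covariate, 24 without CreERT2/+ 3 and 2 with 7SK as a covariate. With that covariate the atrial list did not pass (adjusted p = 0.541, the highest of its 24 alternatives), nor did Med18 (0.153) or Otx1 (0.138). The lists called were 3 without CreERT2/+ 2, CreERT2/del 1 or CreERT2/del 3.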

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

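The tests of explanations in this part, the omission of the 3 libraries, the 7SK covariate, the interaction values without single libraries and the reading of other splits of the samples were all chosen or written down only after the results were seen; the rule for a sample far from the others and the interaction test were fixed beforehand.

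Genes higher in the 3 altered genotypes than in WT form the first pattern: of the 16 genes called higher in del/+, 13 were also called in CreERT2/del, and 5 of the 16 are histone or small noncoding genes. Kcna1 kept its call in 3 of 3 comparisons with WT when 7SK was a covariate (del/+ 5.46 ± 0.36 before and 3.68 ± 0.46 after). The level of 7SK alone therefore did not account for its change in this model. Recovery of small noncoding RNA as the whole cause for Kcna1 stays open, because 7SK is 1 such gene and is itself among the 16. As a covariate it also overlaps with genotype: it was at most 4.892 log2 CPM in WT (WT 2) and at least 4.955 in the others (CreERT2/+ 3). Med18 in del/+ went from 2.49 ± 0.28 to 1.61 ± 0.54 and lost its call, as the change became smaller and its error larger; the reason for this was not tested. Recovery of small noncoding and histone RNA as a class may still account for part of the pattern: the class median was 0.19 in del/+ against WT over 203 genes, above all of 10000 random lists matched on expression yet under the 0.3 that the test required, and its parts, looked at afterwards, differed (-0.10 for 147 small noncoding and 0.95 for 56 histone genes). The tables argue against an effect graded by the number of altered Tbx5 alleles: it needs the 16 genes to rise again by at least 0.5 in CreERT2/del against CreERT2/+, and their median there was 0.0171 (SD 0.2898), with 8 on each side. The rule of this test was changed after its value was seen, since its first version excluded the effect only at a median of 0 or less. A difference from WT that is as large with 1 altered allele as with both was not tested, and a batch shared by the WT libraries cannot be told apart from their genotype, as the labels give none.

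The second pattern is the 3 libraries low in mitochondrial ribosomal RNA. The tables argue against a few genes taking most of the counts as the whole cause: this would shift all other genes of a library alike, but the median within-genotype differences of the longest and shortest genes lay 0.845 apart (SD within these genes 0.596). This test replaced an earlier one, the gap on the first principal component without the 6 most abundant genes (34.6 before and 33.2 after), because values already scaled by TMM factors hardly change when these genes are dropped. The tables also argue against genotype, which held 2.35% of that component's variance. Gene length bias fits the values it was tested on: the within-genotype difference of these libraries followed gene length across genes with a Spearman rho of 0.437, from a median of -0.44 in genes of up to 2092.75 bases to 0.41 in genes of at least 5556 bases. A candidate explanation is therefore a difference in RNA fragments or library making between these and the other 13 libraries, which these data do not separate from a difference between embryos.

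The third pattern is the 8 genes lower in CreERT2/del than in CreERT2/+, with a median of -1.94 (Cacna2d2, Ifltd1 and Tmem163 among them, named after their values were seen). Fewer cardiomyocytes would lower the sarcomere genes too, but their median was 0.17 (SD of the members 0.299), so they were not lower as a set. For less atrial tissue as the whole cause, the test asked whether the other 8 atrial markers fell as much, and their median was -0.61 (SD 0.662). The pattern's genes were chosen for their falls in this same comparison and these markers did not pass in it. A smaller fall of these markers therefore follows from the choice, and this explanation stays open. All 10 atrial markers were negative, from -2.92 to -0.01. A first version of this test asked whether all 10 fell unequally (Cochran's Q of 87.8 on 9 degrees of freedom). It was replaced because 2 of the 10 are among the pattern's own genes. An effect graded by altered alleles may hold and stays open, as 7 of the 8 were lower in del/+ than WT with a median of -0.25, short of the -0.3 that the test required by less than the SD of the genes (0.536); the rule of this test was changed in the same way. A change in conduction tissue or in Tbx5 target genes within cardiomyocytes was not tested.

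Other splits of the 8 libraries of each comparison into 4 and 4 were run in the same way (35 splits, the real one included). For the interaction, 100 assignments of all 16 libraries to the 4 genotypes were used, the real one included. These counts do not exclude chance: 1 of 35 is the smallest share possible, and no correction was made over the comparisons. Other splits also mix genotypes, so a genotype difference adds to the spread within their groups. The drawn assignments do not test the interaction apart from other genotype differences. The real split called the most genes for CreERT2/del against WT (49 genes, 1 of 35 splits as many, highest other 1). The same held for del/+ against WT (17 genes, 1 of 35, highest other 1) and CreERT2/del against del/+ (3 genes, 1 of 35, highest other 0). It also held for CreERT2/del against CreERT2/+ (11 genes, 1 of 35, highest other 0) and the interaction (6 genes, 1 of 100, highest other 4). It did not hold for CreERT2/+ against WT (5 genes, 4 of 35) or CreERT2/+ against del/+ (0 genes, 35 of 35, highest other 2). The split of WT 2, WT 3, CreERT2/+ 2 and CreERT2/+ 4 against the other 4 called 867 genes, which points to a structure of these samples. It follows their order on the first principal component, on which these 4 lay from -34.2 to -14.4 and the other 4 from -4.69 to 82.0. WT 4 and CreERT2/+ 3, both low in mitochondrial ribosomal RNA, are among the other 4, but the 14 other splits that keep them on 1 side called at most 16 genes, and 11 of them called 0 by edgeR.

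The counts of called lists have the same limits. The real split called the most lists for CreERT2/del against del/+ (7 lists, 1 of 35 splits, highest other 4) and against CreERT2/+ (9 lists, 1 of 35, highest other 7). It did not for CreERT2/del against WT (5 lists, 9 of 35, highest other 7) or del/+ against WT (1 list, 30 of 35, highest other 4). Nor did it for CreERT2/+ against WT (0 lists, 35 of 35, highest other 6) or CreERT2/+ against del/+ (4 lists, 4 of 35, highest other 5). For the interaction it did not either (6 lists, 6 of 100, highest other 8). Single lists were ranked over the splits only where the real split called them, so that choice favours a lowest p there. Taken by itself, a called list had its lowest p in the real split for 5 of 5 lists of CreERT2/del against WT, 1 of 1 of del/+ against WT, 3 of 7 of CreERT2/del against del/+, 6 of 9 against CreERT2/+, 3 of 4 of CreERT2/+ against del/+ and 1 of 6 of the interaction. The others were as low in more splits: against del/+ outflow tract signals and epicardium in 2 of 35, erythroid cells in 8 and endoderm and liver in 13. Against CreERT2/+ they were epicardium and cell cycle in 2 and the integrated stress response in 3, and for CreERT2/+ against del/+ ion channels in 3. In the interaction they were atrial markers and ion channels in 2 of 100, the neighbours of Tbx5 in 3, glycolysis and hypoxia genes in 17 and endoderm and liver in 20.

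By the interaction test, 6 genes in CreERT2/del departed from the sum of the changes in both heterozygotes: the log2 values were -5.37 for Kcna1, -3.68 for Ap3b2, -2.78 for Med18, -3.45 for Otx1, -4.33 ± 0.73 for 7SK (adjusted p = 0.0192) and -4.55 ± 0.83 for Unc5d (adjusted p = 0.0446). In fits that left out 1 library, 7SK did not pass without WT 1, 3 or 4, del/+ 2, CreERT2/+ 1 or 2 or CreERT2/del 1 or 4 (adjusted p from 0.0515 to 0.106). Unc5d did not pass without WT 1, 2, 3 or 4, del/+ 2 or 4, CreERT2/+ 1, 2 or 4 or CreERT2/del 2 or 4 (0.0557 to 0.153). Without del/+ 2 the values were -3.72 for 7SK and -3.82 for Unc5d, and without CreERT2/del 1 the Unc5d value was -5.20. All but Ap3b2 were also called higher in del/+ than in WT, and a shift shared by the WT libraries alone would give such values too, so they do not show by themselves that the alleles act on each other.

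Among library measures, 3 of 20 groups of 4 had a library far from the others, where chance gives about 1 in 20. These were WT 4 in mitochondrial ribosomal RNA (60.6%, the others from 67.9% to 69.3%), del/+ 3 on the first principal component (-12.0, nearest -4.54) and CreERT2/del 3 on the same component (36.0, nearest -10.0).

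Among the 22 named genes 6 of 88 groups had such a library, with 4.4 given by chance. Tbx5 was at 39.2 CPM in CreERT2/+ 3 (nearest 20.6), Kcna1 at 1.23 CPM in WT 1 (nearest 0.763) and at 12.97 in CreERT2/+ 3 (nearest 25.8), and 7SK at 29.6 CPM in WT 2 (nearest 13.3) and 31.0 in CreERT2/+ 3 (nearest 137.3). BC053393 was at 0.0981 CPM in CreERT2/del 1 and 0 in the other 3.

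Among the gene lists 5 of 104 groups had such a library, with 5.2 given by chance. In mean log2 CPM, ion channels were at 3.77 in WT 4 (nearest 3.33), epicardium at 3.30 in CreERT2/+ 4 (nearest 3.50), endoderm and liver at 2.22 in del/+ 1 (nearest -2.04) and -1.22 in CreERT2/del 3 (nearest 0.05), and the integrated stress response at 2.36 in del/+ 4 (nearest 2.72).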

How the results depend on the processing

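The removal of the 6 most abundant genes, the omission of the 3 libraries low in mitochondrial ribosomal RNA and the covariates for that share and for 7SK were chosen after seeing the data; the other alternatives were fixed beforehand. Of 1512 alternative values over 53 results for named genes, 1411 kept direction and side of the threshold, 97 kept direction and no longer passed, and 0 reversed a called change; the other 4 were Tbx5 values that changed sign and did not pass in any of these models; Gja5 in CreERT2/del and Kcna1 passed under every alternative run, and Ap3b2 under all but the stricter filter, which removed it before testing. Tbx3 (8 alternatives) in CreERT2/del against WT, Tesc (10) in CreERT2/+ and Tnc (15) against CreERT2/+ were among the results that lost their calls most often. Other size factors, the erythroid genes, the 6 genes and Xist moved no count by over 1.5 times. In the exact test the Tbx5 differences kept their direction and side of the threshold except without WT 1. Where the cause is not given by fewer genes or libraries tested, it was not tested. Depth was not varied, so what it limits was not tested; in simulated data 25% of 2-fold changes were recovered.

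In the order CreERT2/del, del/+ and CreERT2/+ against WT, CreERT2/del against del/+ and against CreERT2/+, CreERT2/+ against del/+, and interaction, the counts were 49, 17, 5, 3, 11, 0 and 6. With no filter they were 189, 120, 73, 65, 92, 36 and 73, and with DESeq2 121, 41, 21, 22, 43, 1 and 16. With limma-voom they were 121, 29, 21, 9, 18, 0 and 13. Without the 3 libraries the first 4 were 95, 43, 33 and 16 and the last 24; with their share as a covariate all but CreERT2/+ against del/+ moved, to 129, 43, 21, 6, 27 and 15. With 7SK as a covariate, the 3 against WT were 18, 1 and 2 and the interaction 2. The stricter filter gave 13, 10 and 5 for CreERT2/del against WT, del/+ against WT and CreERT2/del against CreERT2/+. Only the groups compared gave 37 for del/+ against WT, 13 for CreERT2/del against del/+ and 2 against CreERT2/+. Every gene called in the main model was also called with DESeq2 and with no filter.

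Leaving out 1 library gave 24 to 99, 13 to 38, 3 to 34, 2 to 6, 3 to 21, 0 to 0 and 4 to 24 genes in the same order, each highest without CreERT2/+ 3 except where all were 0. The Tbx5 differences ran from 0.49 to 0.76 in del/+, 0.02 to 0.38 in CreERT2/+ and 0.05 to 0.32 in CreERT2/del; the del/+ value of 0.76, without WT 1, passed the exact test. The correlation of the heterozygote effects was 0.525, and 0.043 with the WT libraries split 2 and 2.

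The lists called were 5, 1, 0, 7, 9, 4 and 6. An estimated correlation gave 0 for del/+ against WT, 3 and 5 for CreERT2/del against del/+ and CreERT2/+, 0 for CreERT2/+ against del/+ and 1 for the interaction. 7SK as a covariate gave 8, 3 and 2 against WT and 1 for the interaction. Without the 3 libraries the counts were 0 for del/+ and 2 for CreERT2/+ against WT and 4 for CreERT2/del against del/+. No filter gave 1 for CreERT2/+ against WT and 3 for the interaction, and the stricter filter 1 and 1. Leaving out 1 library gave 5 to 8, 0 to 2, 0 to 2, 5 to 7, 7 to 10, 1 to 5 and 3 to 7.

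The replicate numbers did not clearly pair the samples: same-number libraries had correlations of their deviations from -0.325 to 0.487, with 3 of 24 pairs above 0.1. The highest were 0.487 for CreERT2/+ 3 with CreERT2/del 3 and 0.310 for WT 2 with CreERT2/+ 2. Yet 8 of 16 libraries correlated best with their own number, more than random matching would give, so a pairing of some libraries is not excluded. With the replicate block the gene counts were 41, 20, 5, 3, 11, 0 and 6, and the lists 6, 0, 0, 6, 9, 4 and 6; the trabecular list in del/+ was no longer called, nor were Tbx3 in CreERT2/del and Tesc in CreERT2/+ against WT. For the interaction, a fit with only the groups compared was not run, since it needs all 4.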

Other observations

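The Fisher test of genes near Tbx5, the histone medians, the removal of the 6 most abundant genes, the count ratios and the genes singled out in this part were chosen after the results were seen; the gene lists, the calls by edgeR and the other size factors were fixed beforehand. Transcripts of tissues next to the heart varied between libraries of 1 genotype. Albumin (Alb) was at 51.4 CPM and alpha-fetoprotein (Afp) at 154.0 CPM in del/+ 1, while the other del/+ libraries had at most 0.04 and 2.71 CPM. In CreERT2/del, Alb was at 0.0981, 5.05, 0.327 and 3.21 CPM and Afp at 6.52, 17.2, 2.92 and 21.5 CPM in libraries 1 to 4, and WT 3 had 24.8 CPM of Afp. Colec10, Lhx2 and Barx1, named after their values were seen, were among the 27 genes that rose in CreERT2/del: they had 181, 212 and 187 counts in those libraries and 2, 6 and 9 in WT, ratios of 92.0, 35.9 and 21.1 with 95% counting intervals of 25.1 to 765.3, 16.2 to 98.96 and 10.9 to 46.9. In del/+ 1, Colec10 was at 0.724 and Lhx2 at 0.953 CPM.

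The median log2 change of the 56 tested histone genes was 1.00 in CreERT2/del, 0.95 in del/+ and 1.04 in CreERT2/+ against WT, and lay between 0.95 and 1.04 with other size factors and without the 6 most abundant genes, while the cell cycle list was not called in any of the 3. These comparisons share the WT libraries, no test of the histone genes as a set was run, and CreERT2/+ 3 lay at the level of WT for Hist1h4c (1.735 CPM, WT 1.367 to 2.907) and below it for Hist2h2ac (9.831 CPM, WT from 10.94). Myh11, smooth muscle myosin, and Edn1, endothelin 1, were among the genes that rose in CreERT2/del, by 1.88 ± 0.38 and 1.12 ± 0.24, and are named after their values were seen.

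Tesc and Tbx3 lie 1.77 and 0.15 Mb from Tbx5 on chromosome 5, and flanking sequence carried with the altered alleles might change genes nearby. Of 210 tested genes within 10 Mb of Tbx5, 6.19% had an unadjusted p under 0.05 in CreERT2/del against WT, against 5.66% of the other 14402. Fisher's exact test, two-sided, gave p = 0.654, so these counts do not settle the question.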
